A study of Homo sapiens with 24 samples.

How the data were processed

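Gene counts came from RNA sequencing of 24 libraries of primary human epidermal keratinocytes in 8 groups of 3: medium, HGF, IL-17A, TNF-α, IL-22, an interleukin at 100 ng that the labels do not name (IL100ng), and calcium at 0.03 and 1.3 mM. The authors deposited 1 table of raw read counts per Ensembl gene, with 1 column per library, and no normalization was applied to the deposited counts. Per the submitters' processing notes, FastQC 0.11.8, STAR 2.4.2a, Subread 1.5.0, featureCounts and the human genome build GRCh37 were used. The annotation release, the strand setting and any filter were not given in the sources used here. Reads of antisense or overlapping genes (such as LURAP1L-AS1 and RPSAP52), and of near-identical copies (the SPRR2, KRT6, DEFB4, S100A7 and SERPINB3 and SERPINB4 genes), may therefore be divided between genes in a way that cannot be checked here. Of 35568 genes in the table, 35438 were matched to a symbol and 9734 had no counts in any library. The symbols CCL5, UHRF1, MMP12, MMP28, ACACA and PECAM1, which gene lists held, were not analysed here.

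Depth ranged from 27.0e6 to 41.6e6 counts in 23 libraries, and TNF-α replicate 2 had 3.02e6. That library was kept in the fit, as planned before the data were examined, and results without it are given as an alternative, planned for the comparisons with TNF-α and chosen afterwards for the others. No pair of libraries was close enough in its counts to be a duplicate. The lowest chi-square per degree of freedom was 2.06 over the 24 pairs within groups and 4.19 over the 252 pairs between groups. The replicate numbers were not treated as pairs, since no label ties equal numbers together.

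Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with enough counts by filterByExpr (15551) were scaled by TMM and fitted with robust quasi-likelihood in 1 model with a mean per group, which leaves 16 residual degrees of freedom. All groups thus share 1 estimate of the spread. The comparisons were HGF, IL-17A, TNF-α, IL-22 and IL100ng against medium, high against low calcium, HGF against IL-17A, TNF-α and IL-22, and low calcium against medium. Each used a 2-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes, and genes with an adjusted p under 0.05 were called. CPM are counts scaled to the TMM-adjusted library size, given as mean ± SD of 3 libraries, and fold changes are log2. Their standard error was computed back from the fold change and the p-value of the F test, so it holds no information beyond these. For a gene without counts in a group, folds were computed against a floor of 3 counts over the group. Shares of counts in a single library have 95% Wilson intervals. A gene was distinct for HGF when called against medium and called in the same direction in all 3 direct tests.

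Gene lists (34) on keratinocyte differentiation, barrier, inflammation, signalling, division, stress, metabolism and markers of other cell types were fixed before the data were examined. The genes of a list are called by its name below, although some lists were broader than their names. The neutrophil chemokine list also held CSF2, CSF3, IL6 and LIF, and the antimicrobial and S100 list also held C3, CFB, NFKBIZ and ZC3H12A. Lists could share genes, such as CXCL14 (other chemokines and basal keratinocyte) and BCL3 (NF-κB and STAT3 responses). The 33 lists with at least 3 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the lists of a comparison. The tests were repeated with an estimated correlation, and with fry, which asks whether the genes of a list move 1 way without comparing them with other genes. For every comparison the correlation was estimated from all 24 libraries, TNF-α replicate 2 among them. Counts of list members that changed are given over all genes and adjusted over the list alone.

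Genes were named by a rule fixed beforehand: per comparison, the 10 largest increases and 10 largest decreases among called genes with at least 1 CPM in a group and with the libraries of the 2 groups fully separated; up to 4 members of a described list with the smallest adjusted p; and the receptor genes MET, IL17RA, IL17RC, IL22RA1, IL10RB, TNFRSF1A and TNFRSF1B. The 10 largest increases and decreases of the distinct set were added, under the same limits in HGF against medium. Genes named outside this rule are said to be. Some genes that met it are not reported here.

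For overlaps between comparisons with the shared medium libraries, 20 simulations of unchanged groups and the overlap of independent lists were computed. Other choices, listed before the data were examined, were DESeq2 size factors and upper quartile scaling in edgeR, no filter and a filter of at least 10 reads in 3 samples, the DESeq2 1.42.0 Wald test, limma-voom, a fit of only the groups compared, and leaving out each replicate in turn. The methods were tested on simulated counts for HGF against medium over 15551 genes with 200 genes changed. Of the genes changed 1.5-fold, 2-fold and 4-fold, edgeR recovered 62.7, 95.5 and 100%, with 5 false calls. DESeq2 recovered 67.2, 95.5 and 100% with 16 false calls, and limma-voom 64.2, 95.5 and 100% with 6. The simulated changed list was called by camera and none of 33 unchanged lists was called by camera or fry. Genes were drawn independently there, so this does not show how camera or fry treat lists of correlated genes.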

Results

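The series measured messenger RNA by sequencing in primary human epidermal keratinocytes, the cells that form the outer layer of the skin, after 24 h of stimulation in culture. It held 24 libraries in 8 groups of 3. The untreated group was in medium alone, and 4 groups received a named factor: hepatocyte growth factor (HGF) at 100 ng/ml, interleukin 17A (IL-17A) at 200 ng/ml, tumour necrosis factor alpha (TNF-α) at 10 ng/ml or interleukin 22 (IL-22) at 50 ng/ml. Another group was labelled only as an interleukin at 100 ng and is called IL100ng here, because no label says which interleukin it was. The last 2 groups were labelled with calcium at 0.03 mM (low calcium) or 1.3 mM (high calcium). The calcium concentration in the other groups was not given in the sources used here. No label says whether the 3 replicates of a group came from separate cultures or donors, so every p-value below measures only the spread between these samples. For each gene named below with an adjusted p under 0.05, all 3 libraries of 1 group lay above or below all 3 of the other, except FASN in the TNF-α group. Genes given as the largest changes were ranked by fold change among called genes with at least 1 CPM (a count scaled to the size of the library) in a group and such full separation.

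Sequencing depth was even in 23 libraries, which held between 27.0e6 and 41.6e6 gene counts. TNF-α replicate 2 held 3.02e6, so 1 CPM stood for 3.02 counts there and for at least 27.0 counts in every other library. Mitochondrial ribosomal RNA took 21.8% of the counts of TNF-α replicate 2 (95% Wilson interval 21.8 to 21.9%), against 0.329 to 0.708% in the other 23 libraries. Protein-coding genes took 74.8% of its counts (95% Wilson interval 74.7 to 74.8%), against 98.3 to 98.7% elsewhere, and its 10 most abundant genes took 30.7% (30.7 to 30.8%), against 9.07 to 12.8%. These intervals cover counting error only. In a principal component analysis of the tested genes, the first component carried 44.9% of the variance and set both calcium groups apart from the other 6 groups. The second component carried 18.2% and set TNF-α replicate 2 apart from the other libraries.

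**Figure D1:**
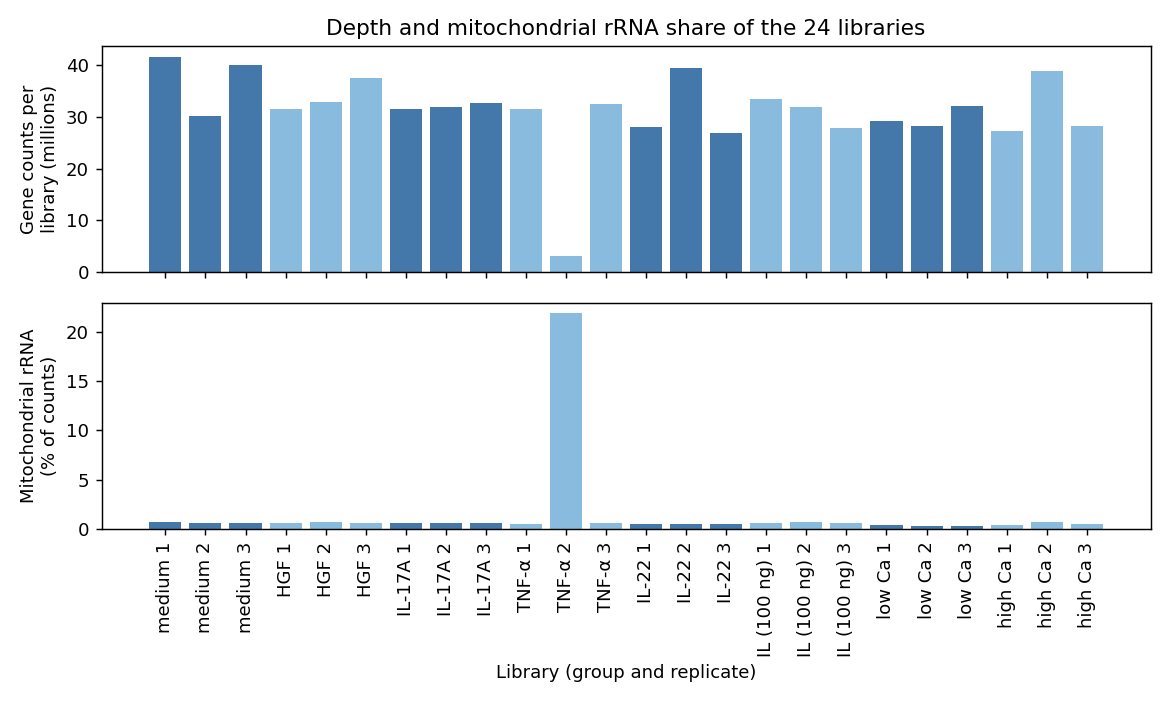
Bars show, for each of the 24 libraries, the total gene counts (upper axis) and the share of counts from mitochondrial ribosomal RNA in percent (lower axis), with shades alternating between groups. TNF-α replicate 2 has 3.02e6 counts and a mitochondrial ribosomal RNA share of 21.8%, while the other 23 libraries have at least 27.0e6 counts and a share of at most 0.708%.

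Stimulation changed from 312 to 3845 of the 15551 tested genes against medium at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). HGF changed 3845 genes, IL-17A 3291, IL100ng 1738, TNF-α 1393 and IL-22 312. High calcium differed from low calcium in 2321 genes. Because all groups shared 1 estimate of the spread, TNF-α replicate 2 affected every count. With that library left out of the fit, the counts were 5537 for HGF, 5082 for IL-17A, 3226 for IL100ng, 2503 for TNF-α, 767 for IL-22 and 3936 for calcium. Leaving it out was planned for the comparisons with TNF-α and was chosen after the data were seen for the others. The order of the 5 stimuli was the same with 24 and with 23 libraries, but with only the groups compared in the fit IL-17A (6281) lay above HGF (5844), and IL-22 (1634) above TNF-α (26).

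**Figure D2:**
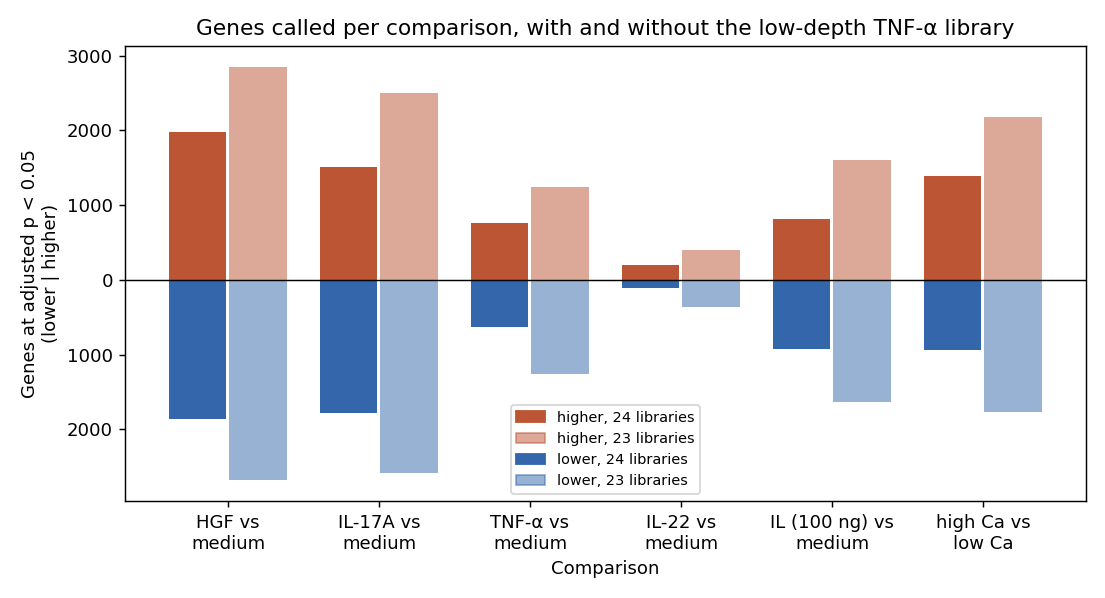
Bars show the number of genes at an adjusted p under 0.05 in 6 comparisons, higher in the first group above the line and lower below it, from all 24 libraries (dark) and from the 23 left without the low-depth TNF-α library (pale). HGF has 3845 genes in the first fit and 5537 in the second, and IL-22 has 312 and 767.

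HGF is a secreted growth factor that signals through the receptor tyrosine kinase MET and acts on epithelial cells. The comparison with medium addresses what HGF does to keratinocytes. Genes of the G2 and M phases of division, of feedback on the ERK kinase pathway and of mesenchymal features were higher in HGF-treated cells, while genes of spinous differentiation were lower. The most reduced gene was IGFBP3, which encodes a binding protein for insulin-like growth factors. Its mean fell from 474 ± 12.8 CPM in medium to 11.6 ± 5.60 CPM in HGF (SD, n = 3 each), a log2 fold change of -5.36 ± 0.267 (SE, edgeR adjusted p 4.10e-12). IGFBP5, a second member of that family, fell from 94.2 to 7.36 CPM (log2 fold change -3.68, edgeR adjusted p 4.36e-11). HSPB3, ADH7, WNT4, SLC47A2 and LMO1 were also among the 10 largest decreases, with log2 fold changes between -4.01 and -2.61. The most increased gene was MYH15, from 0.281 ± 0.184 to 8.5 ± 0.795 CPM (log2 fold change 4.87 ± 0.374, edgeR adjusted p 4.59e-10). Among genes with at least 1 CPM in a group, TFPI2 followed with a log2 fold change of 3.67 ± 0.184 (edgeR adjusted p 3.47e-13), then LINC00973 with 3.19, NTSR1 with 3.13, the transcription factor ETV1 with 2.93 and the cytokine CSF2 with 2.91. Of the 3845 genes called, 1979 were higher and 1866 lower, and 751 changed at least 2-fold. The 3 HGF libraries lay all above or all below the 3 medium libraries for 7605 genes (48.9%), where chance gives 10%. A fit of the HGF and medium groups alone called 5844 genes.

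Genes of cell division rose with HGF. Each of the 32 tested genes of the G2 and M phases was higher, with a median log2 fold change of 0.99 (camera adjusted p 6.81e-58, and 0.00107 with an estimated correlation). All 32 also passed when adjusted over the list alone. AURKA rose from 19.2 ± 0.258 to 50.6 ± 0.592 CPM (log2 fold change 1.40, edgeR adjusted p 4.12e-12) and PLK1 from 21.1 ± 0.568 to 53.2 ± 5.17 CPM (1.34, edgeR adjusted p 3.18e-11). Of 26 S-phase genes, 13 rose and 1 fell over all genes and likewise when adjusted over the list alone, with a median of 0.24. That call was lost with an estimated correlation (adjusted p 0.000762 and 0.404). CDC6, CDC45 and RRM2 rose by 0.60, 0.64 and 0.62 on the log2 scale, while E2F2 fell by 1.09.

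Most of the feedback inhibitors and transcription factors induced by ERK signalling were raised by HGF. Of 27 such genes, 18 rose and 2 fell over all genes, against 19 and 2 when adjusted over the list alone (median log2 fold change 0.57, camera adjusted p 6.72e-12, and 0.0394 with an estimated correlation). ETV5 rose from 10.7 ± 1.07 to 43.1 ± 0.955 CPM (log2 fold change 2.02 ± 0.101, edgeR adjusted p 3.47e-13), and DUSP4 and SPRY2 rose by 1.37 and 1.47. EPHA4 went the other way, from 122 to 38.9 CPM (edgeR adjusted p 9.43e-14). So did the transcription factor EGR1, named outside the rule (log2 fold change -1.49, edgeR adjusted p 5.50e-06). Growth factor genes rose in 14 of 25 cases and fell in 4 (15 and 4 when adjusted over the list alone), with a median of 0.43 (camera adjusted p 0.00136, and 0.0122 with an estimated correlation). VEGFC, PGF and HBEGF rose by 1.13, 1.3 and 0.91 on the log2 scale, and EPGN fell by 1.11. Among 11 mesenchymal genes 5 rose, in both adjustments, and none fell (median 0.55, camera adjusted p 0.000530, and 0.0286 with an estimated correlation). VIM, which encodes vimentin, rose from 136 ± 1.76 to 464 ± 45.2 CPM (log2 fold change 1.77, edgeR adjusted p 4.52e-11), and CDH11 and SNAI2 rose by 0.98 and 0.55.

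Genes of the unfolded protein and ATF4 responses also rose with HGF. Of 18 genes, 15 rose and 1 fell (17 and 1 when adjusted over the list alone), with a median log2 fold change of 0.88. Its camera adjusted p was 1.08e-09, and 0.0537 with an estimated correlation, so this call was lost there. SDF2L1 rose by 1.64 (edgeR adjusted p 7.00e-08) and CHAC1 by 1.07, while ATF3 fell by 1.23. In a list of 25 proteases and inhibitors, 10 rose and 4 fell (11 and 6 when adjusted over the list alone). That call (camera adjusted p 0.0251) was lost with an estimated correlation (0.383) and without HGF replicate 3 (0.0528). PLAU rose from 415 to 704 CPM, and PLAT and ADAM19 rose by 1.60 and 1.57 on the log2 scale (edgeR adjusted p 1.30e-08 and 1.64e-07).

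Spinous differentiation, the programme of keratinocytes that have left the basal layer, was lower with HGF. Of 19 genes, 12 fell and none rose in either adjustment (median log2 fold change -0.78, camera adjusted p 3.25e-12, and 0.0105 with an estimated correlation). KRT10 fell from 2690 ± 99.8 to 1258 ± 130 CPM (log2 fold change -1.10, edgeR adjusted p 1.06e-08), and KRT1, DSC1 and KRT77 fell by 1.08, 1.2 and 1.42. Basal keratinocyte genes did not move as 1 block: 8 of 20 fell, among them IGFBP3, ASS1 and CXCL14, while 2 rose, including DCBLD2 from 306 to 626 CPM. The counts were the same when adjusted over the list alone, with a median of -0.12 (camera adjusted p 0.00571, and 0.0481 with an estimated correlation). Barrier lipid genes fell in 8 of 22 cases (11 when adjusted over the list alone) with a median of -0.22. That call (camera adjusted p 0.0421) was lost with an estimated correlation (0.564), without HGF replicate 1 (0.0697), without medium replicate 2 (0.111) and without medium replicate 3 (0.118). SPTLC3 fell by 0.57 on the log2 scale (edgeR adjusted p 8.70e-06).

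Inflammatory genes split in their response to HGF. Of 9 tested genes of the neutrophil chemokine list, which also held CSF2, CSF3, IL6 and LIF, 4 rose and none fell, in both adjustments. That list's camera adjusted p was 0.00704, and 0.104 with an estimated correlation, where the call was lost. CXCL1 rose from 12.6 ± 0.784 to 27.9 ± 5.95 CPM (log2 fold change 1.15, edgeR adjusted p 2.28e-07) and CXCL8 from 1.89 to 4.51 CPM (1.25, edgeR adjusted p 1.78e-05). Of 9 other chemokines, 4 fell in both adjustments (median log2 fold change -0.69, camera adjusted p 0.00136, and 0.0481 with an estimated correlation). CXCL14 fell from 1629 ± 139 to 300 ± 43.0 CPM (log2 fold change -2.44, edgeR adjusted p 4.55e-11), and CXCL16 and CXCL10 fell by 1.03 and 1.36. CXCL14 is also in the basal keratinocyte list, so the calls of these lists rest in part on the same gene. Interferon-response genes fell in 21 of 30 cases (25 when adjusted over the list alone), with a median of -0.70. The camera adjusted p was 6.17e-14, and 0.0537 with an estimated correlation, so this call was lost there. MX1 fell from 114 ± 10.2 to 41.9 ± 3.96 CPM (log2 fold change -1.44, edgeR adjusted p 1.40e-08), and GBP1 fell by 1.28.

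The receptor genes moved little. MET, the HGF receptor, was at 238 ± 12.5 CPM in medium and 310 ± 9.59 CPM with HGF (log2 fold change 0.38, edgeR adjusted p 0.00183). IL17RC fell by 0.37 (edgeR adjusted p 0.00746). IL17RA, IL22RA1, IL10RB and TNFRSF1A did not pass, with edgeR adjusted p from 0.0899 to 0.4, but IL17RA did without TNF-α replicate 2 (log2 fold change -0.20, 0.00982) and in a fit of HGF and medium alone (0.0165). TNFRSF1B had too few counts to be tested.

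**Figure D3:**
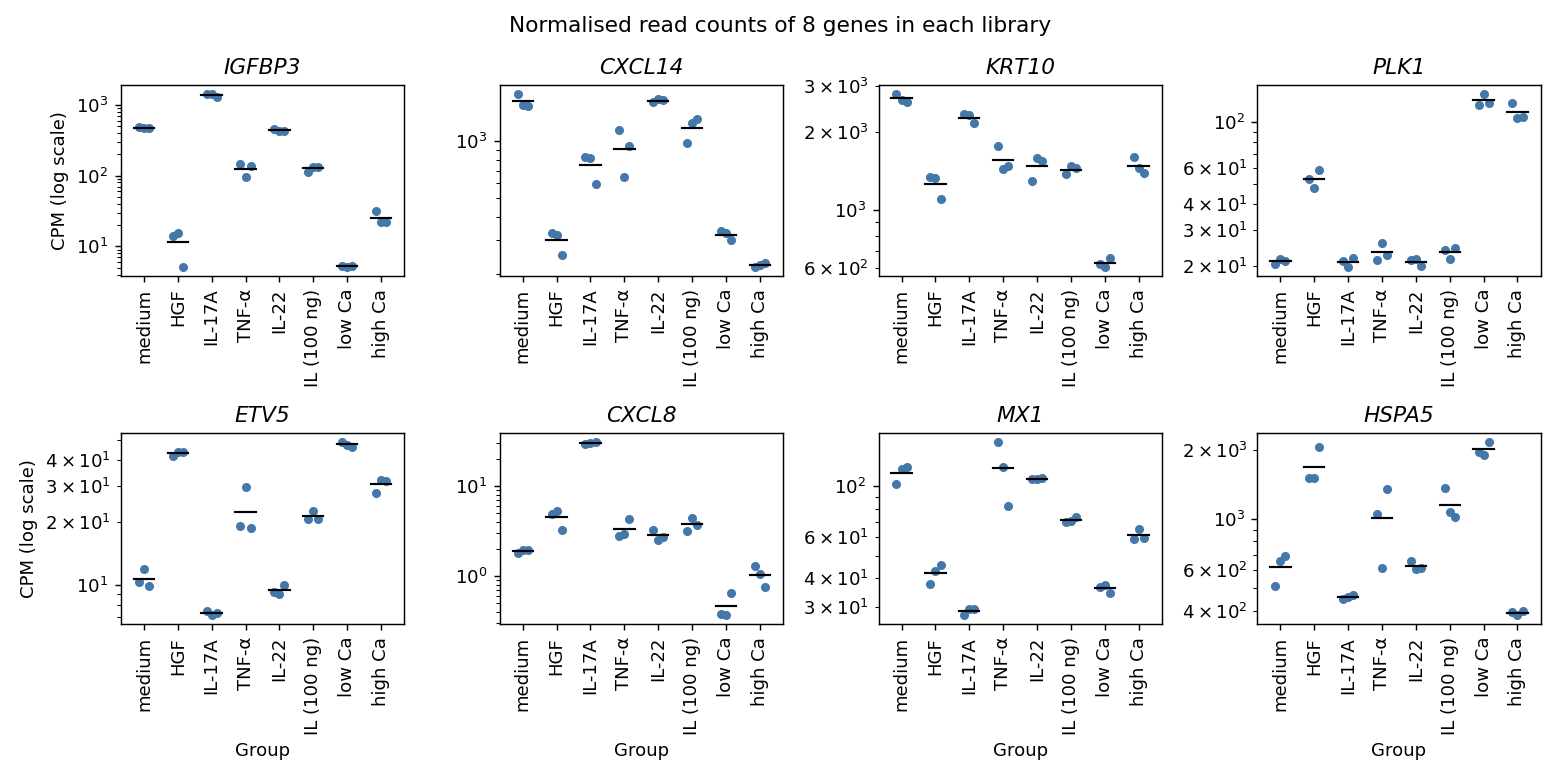
Points are single libraries and lines are group means of 8 genes in CPM on log axes, for 8 groups of 3 libraries. IGFBP3 lies at 11.6 CPM in HGF against 474 CPM in medium and 1389 CPM in IL-17A, and PLK1 lies at 53.2 CPM in HGF against 21.1 CPM in medium.

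The title of the series sets HGF apart from IL-17A and TNF-α, so HGF was also compared with each of the other named factors directly. HGF and IL-17A differed in 5212 genes, of which 2800 were higher with HGF. HGF and TNF-α differed in 2367 genes (1149 higher with HGF, edgeR), and HGF and IL-22 in 3832 (1952 higher). At least 2-fold differences were found in 1248, 349 and 805 genes. A fit of HGF and TNF-α alone, with the low-depth library among its 6, called 214 genes in place of 2367. Libraries of the 2 groups were separated for 8523 genes (54.8%) against IL-17A, 4318 (27.8%) against TNF-α and 7309 (47.0%) against IL-22, where chance gives 10%.

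Genes of the G2 and M phases separated HGF from all 3 factors. Each of the 32 G2 and M phase genes was higher with HGF than with IL-17A (median log2 difference 1.11), than with TNF-α (1.15) and than with IL-22 (1.06). With an estimated correlation the camera adjusted p were 0.00166, 1.36e-05 and 0.000684. The S-phase list did not do so: its calls against IL-17A (16 of 26 higher, 2 lower) and IL-22 (14 higher, 1 lower) were lost with an estimated correlation (0.4104 and 0.287), and it was not called against TNF-α (camera adjusted p 0.2899). AURKA stood at 50.6 CPM in HGF, 23.1 in IL-17A, 20.3 in TNF-α and 20.3 in IL-22 (edgeR adjusted p 4.36e-11, 6.95e-10 and 7.81e-12). ETV5 was higher with HGF by 2.57, 1.08 and 2.20 on the log2 scale (edgeR adjusted p 3.22e-15, 7.55e-08 and 1.86e-13). Against TNF-α the ERK target list rose in 11 of 27 cases and fell in 3 (12 and 4 when adjusted over the list alone). That call (camera adjusted p 0.00817) was lost with an estimated correlation (0.541), without TNF-α replicate 1 (0.173) and without replicate 3 (0.192). Without the low-depth TNF-α replicate 2, 14 were higher and 3 lower with HGF, with a camera adjusted p of 7.76e-06 at the preset correlation. The estimated correlation was not repeated without that library. VIM was higher with HGF than with IL-17A by 2.37 (464 against 89.9 CPM, edgeR adjusted p 1.48e-13) and than with IL-22 by 2.08 (110 CPM, edgeR adjusted p 3.03e-12). IGFBP3 had log2 differences of -6.91 against IL-17A, -3.47 against TNF-α and -5.25 against IL-22 (edgeR adjusted p 4.99e-14, 4.19e-09 and 3.03e-12).

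Antimicrobial and neutrophil chemokine genes were lower with HGF than with IL-17A. All 18 tested genes of the antimicrobial and S100 list, which also held NFKBIZ, were lower with HGF than with IL-17A (median log2 difference -2.94, camera adjusted p 7.02e-48, and 1.08e-05 with an estimated correlation). DEFB4A, which encodes a beta-defensin, had no counts with HGF and 12.3 ± 0.189 CPM with IL-17A, at least 431-fold higher with a floor of 3 counts over the group. IL36G was at 21 CPM with HGF and 540 CPM with IL-17A (log2 difference -4.69, edgeR adjusted p 1.47e-13), and NFKBIZ at 40.9 and 321 CPM (-2.97, edgeR adjusted p 2.97e-16). Each of the 9 tested genes of the neutrophil chemokine list was lower with HGF than with IL-17A (median -2.73, camera adjusted p with an estimated correlation 0.000480). Oxidative stress genes of the NRF2 list also differed there (8 of 15 lower, 3 higher, against 11 and 3 when adjusted over the list alone), but that call (camera adjusted p 0.0462) was lost with an estimated correlation (0.115), without HGF replicate 3 (0.0511) and without IL-17A replicate 1 (0.0539). Against IL-22, 11 of 18 antimicrobial genes were lower with HGF and 1 was higher (13 and 1 when adjusted over the list alone). Against TNF-α neither the antimicrobial nor the neutrophil chemokine list was called (camera adjusted p 0.563 and 0.343), and against IL-22 the neutrophil chemokine list was not (0.123). Against IL-22, S100A7A differed by -3.76 and SOCS3 by -2.26 (edgeR adjusted p 1.05e-12 and 1.84e-10). Against TNF-α, 9 of 19 genes of the NF-κB response were lower with HGF and none was higher (9 and 1 when adjusted over the list alone, median -0.28, camera adjusted p 0.000527, and 0.0259 with an estimated correlation). TNFAIP3 was at 74.2 CPM with HGF and 127 CPM with TNF-α (edgeR adjusted p 1.53e-07). MET was higher with HGF than with IL-22 by 0.66 (310 against 196 CPM, edgeR adjusted p 2.41e-06) and did not pass against IL-17A (edgeR adjusted p 0.0792) or TNF-α (0.0970). It did pass against both without TNF-α replicate 2 (log2 differences of 0.20 and 0.33, edgeR adjusted p 0.00414 and 0.000292).

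A gene was called distinct for HGF when it changed against medium and differed in the same direction from IL-17A, TNF-α and IL-22 in the direct tests. This held for 1182 genes, 30.7% of those changed by HGF, with 669 higher and 513 lower and 373 changed at least 2-fold. IL100ng was not part of this rule, and the rule does not require a gene to be unchanged in the other groups. IGFBP3 met it, for example, although it was also lower than in medium (474 CPM) with TNF-α (126 CPM) and IL100ng (127 CPM). With TNF-α replicate 2 left out, 1634 genes met the rule, and with each pair of groups fitted alone 193 did. All 32 tested G2 and M phase genes were among the 669 higher ones, while 5 of 26 S-phase genes were among the higher and 1 among the lower. The distinct set also held 9 higher and 2 lower of 27 ERK targets, 9 higher and 1 lower of 18 genes of the unfolded protein and ATF4 responses, and 7 lower of 19 spinous genes. Under the limits given at the start, the 10 largest increases among them included MYH15, TFPI2, NTSR1 and ETV1, and also FOXA2 (log2 fold change against medium 2.38, edgeR adjusted p 6.48e-06) and TGM2 (2.29, from 9.63 to 46.9 CPM, edgeR adjusted p 6.50e-10). Under the same limits, the 10 largest decreases included IGFBP3, IGFBP5, WNT4, CXCL14 and LGI2 (-2.45, from 17 to 3.11 CPM, edgeR adjusted p 1.61e-14).

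Parts of the HGF response were shared with other stimuli. Of the 3845 genes, 1991 changed in the same direction with at least 1 of IL-17A, TNF-α, IL-22 and IL100ng, and without TNF-α replicate 2 the number was 3461 of 5537. HGF and IL100ng shared 613 higher and 700 lower genes, and 19 went in opposite directions. Independent lists of these sizes would share 104 and 111. HGF and TNF-α shared 484 and 477, with 17 opposite, against 97.4 and 75.4 for independent lists. Their sum of 961 was 639 without medium replicate 2, 637 without medium replicate 3, 1868 without TNF-α replicate 2 and 22 with pairs of groups fitted alone. HGF and IL-17A shared 331 and 529 (192 and 214 if independent), while 525 went in opposite directions. The shared sum of 860 was 563 without medium replicate 1. HGF and IL-22 shared 56 and 61 (25.4 and 13.4 if independent), with 52 opposite. For opposite directions no number for independent lists was computed here, so whether these counts also exceed it is not shown. All these comparisons used the same 3 medium libraries, so part of any excess may come from them, and 3 libraries cannot be split. In 20 simulations of unchanged groups against medium, no gene was shared on average. The simulated groups held no real change, so they do not show how far shared medium libraries raise overlaps between groups that do change. Across genes, which are not independent replicates, the log2 fold changes of HGF correlated with those of IL100ng at r = 0.638 (simulated 0.488), TNF-α 0.503 (0.435), IL-22 0.264 (0.486) and IL-17A 0.195 (0.484). The r with TNF-α was 0.379 without TNF-α replicate 3. The matching covariances were 0.135, 0.117, 0.0464 and 0.0564, where the simulated ones lay between 0.0326 and 0.0330. The simulated spread came from the fit that held TNF-α replicate 2. A measured r under the simulated one can therefore not be read as lying below chance.

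IL-17A is a cytokine made by T cells that acts on keratinocytes through IL17RA and IL17RC. The comparison with medium shows a strong rise of antimicrobial peptides, neutrophil chemokines and cytokines of the interleukin 1 and 20 families. SPRR2F, DEFB4A and IL19 had the 3 largest increases, from 0.0192, 0.0165 and 0.0356 CPM in medium to 16 ± 1.81, 12.3 ± 0.189 and 8.56 ± 1.94 CPM (edgeR adjusted p 3.05e-13, 6.02e-10 and 1.66e-09). Their medium levels rested on very few reads, so no fold is given. S100A7A rose by 6.71 ± 0.240 on the log2 scale, from 0.312 to 33.3 CPM (edgeR adjusted p 2.64e-16), and SAA2 and CCL20 by 5.55 and 5.14. All 18 tested genes of the antimicrobial and S100 list, NFKBIZ among them, rose (median 3.15, camera adjusted p 6.44e-95, and 2.29e-07 with an estimated correlation). So did all 9 tested genes of the neutrophil chemokine list (median 3.32, 3.36e-07 with an estimated correlation). The same 18 and 9 passed when adjusted over the list alone. NFKBIZ rose from 37.2 ± 3.34 to 321 ± 16.1 CPM (log2 fold change 3.11, edgeR adjusted p 1.83e-16) and CXCL8 from 1.89 to 30.3 CPM (4.01, edgeR adjusted p 1.83e-14). Of the 3291 genes called, 1509 (45.9%) were higher and 1782 lower, and 566 changed at least 2-fold. With upper quartile scaling the higher share was 32.4%. Groups were separated for 7783 genes (50.0%, chance 10%). With TNF-α replicate 2 left out 5082 genes were called, and with IL-17A and medium fitted alone 6281.

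Cytokine, differentiation and lipid genes followed in the IL-17A group. IL36G rose from 28.2 ± 4.54 to 540 ± 42.4 CPM (log2 fold change 4.26, edgeR adjusted p 1.02e-12) and IL1B from 9.22 to 74.2 CPM (3.01, edgeR adjusted p 7.25e-13). Of 14 genes of the interleukin 1 family, 7 rose and 1 fell (8 and 2 when adjusted over the list alone), and of 5 genes of the interleukin 20 family and interleukin 23, 4 rose in both adjustments. The NF-κB list rose in 10 of 19 cases and fell in 2 (10 and 3 when adjusted over the list alone), and the STAT3 list rose in 13 of 17 (14 when adjusted over the list alone). With an estimated correlation the camera adjusted p of these 4 lists were 0.0269, 5.70e-05, 5.70e-05 and 8.51e-05. Cornified envelope genes rose in 24 of 43 cases and fell in 2 (26 and 3 when adjusted over the list alone, median 0.57, camera adjusted p 1.13e-15, and 0.0269 with an estimated correlation). SPRR2E rose from 128 to 847 CPM, though reads of the near-identical SPRR2 genes may have been divided among them. Barrier lipid genes rose in 16 of 22 cases and fell in 1 (18 and 2 when adjusted over the list alone, 0.0269 with an estimated correlation), including ALOX12B by 1.49 (edgeR adjusted p 9.09e-10). Kallikreins (6 of 11 higher), glycolysis genes (10 of 26 higher, 1 lower) and cholesterol synthesis genes (6 of 25 higher, 1 lower) were called by camera but lost with an estimated correlation (adjusted p 0.144, 0.175 and 0.424). Over each list alone the higher counts were 7, 11 and 6.

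Interferon-response genes fell with IL-17A. Of 30 genes, 26 were lower in both adjustments and none was higher (median log2 fold change -1.06, camera adjusted p 2.67e-35, and 0.00265 with an estimated correlation). IFIT1 fell from 58.7 ± 3.87 to 6.04 ± 1.46 CPM (log2 fold change -3.28, edgeR adjusted p 6.77e-10) and XAF1 from 37.2 to 6.77 CPM (-2.46, edgeR adjusted p 6.77e-14). Basal keratinocyte genes fell in 9 of 20 cases and rose in 2 (11 and 3 when adjusted over the list alone, 0.0269 with an estimated correlation). KRT15 fell by 1.01, while IGFBP3, which HGF lowered, rose from 474 to 1389 CPM (log2 fold change 1.55, edgeR adjusted p 2.40e-05). Of 6 tested genes of a fibroblast marker list, 4 fell in both adjustments (median -0.64, camera adjusted p 0.00213, and 0.0157 with an estimated correlation), led by COL1A2 from 38.1 to 11.8 CPM (edgeR adjusted p 1.89e-07). By camera with all libraries that list was called in no other comparison. Without TNF-α replicate 2 it also fell in HGF and low calcium against medium and in HGF against TNF-α (camera adjusted p 0.0426, 0.0363 and 0.0220), and fry called it in 6 of the 10 comparisons. IL22RA1 rose by 0.46 and IL10RB fell by 0.44 (edgeR adjusted p 0.000397 and 0.00399), and MET, IL17RA and IL17RC did not pass (0.156, 0.286 and 0.186). In a fit of IL-17A and medium alone these 3 did (0.00104, 0.04525 and 0.0235), and MET also passed without TNF-α replicate 2 (0.0159).

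TNF-α is an inflammatory cytokine whose main receptor on epithelial cells is encoded by TNFRSF1A. Neutrophil chemokines, genes of the NF-κB response and targets of ERK signalling were higher than in medium, while spinous genes and IGFBP3 were lower. CXCL1 rose from 12.6 ± 0.784 to 27.5 ± 2.07 CPM (log2 fold change 1.14, edgeR adjusted p 6.04e-06) and ICAM1 from 5.75 to 13.3 CPM (1.15, edgeR adjusted p 6.55e-06). CSF2, SLFN11 and SAA1 rose by 2.65, 2.46 and 2.10 (edgeR adjusted p 2.75e-05, 0.000171 and 1.97e-07). IGFBP3 fell to 126 ± 25.3 CPM (log2 fold change -1.88, edgeR adjusted p 1.39e-05). In all, 1393 genes were called, 765 higher and 628 lower, and 152 changed at least 2-fold. This count was 827 without medium replicate 2, 838 without medium replicate 3 and 2503 without TNF-α replicate 2. In a fit of TNF-α and medium alone it was 26. There CXCL1, ICAM1 and IGFBP3 passed (edgeR adjusted p 0.0384 each), and CSF2, SLFN11 and SAA1 did not (0.0866, 0.0777 and 0.0884). Groups were separated for 3453 genes (22.2%, chance 10%). The 3 largest estimated increases among genes with at least 1 CPM and separated libraries, SNORA73B, PSG7 and SNORD17, owed their size to TNF-α replicate 2: their SD between the TNF-α libraries (60.0, 18.7 and 18.7 CPM) exceeded their means (36.1, 11.4 and 11.9 CPM). Without that library the log2 fold changes were 1.11, 1.07 and 0.92, and SNORA73B and SNORD17 still passed (edgeR adjusted p 0.0131 and 0.0291) while PSG7 did not (0.188). Without medium replicate 2 the edgeR adjusted p of PSG7 was 0.0502, and SNORD17 was at 0.0741, 0.0980 and 0.116 without medium replicates 1, 2 and 3. All 3 also failed with limma-voom (SNORA73B 0.251, PSG7 0.276, SNORD17 0.171) and in the fit of TNF-α and medium alone (0.391, 0.439 and 0.473).

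Several lists moved with TNF-α both with and without the low-depth library. Neutrophil chemokine genes rose in 6 of 9 cases (8 when adjusted over the list alone, median log2 fold change 1.14, camera adjusted p 1.26e-08, and 0.0101 with an estimated correlation), while the list of other chemokines was not called (0.859). The NF-κB list rose in 7 of 19 and fell in 1 (11 and 1 when adjusted over the list alone, camera adjusted p 5.20e-09, and 0.000473 with an estimated correlation). Without TNF-α replicate 2, 11 rose and 2 fell, with a camera adjusted p of 3.27e-07. ERK targets rose in 13 of 27 and fell in 1 (19 and 1 when adjusted over the list alone, 0.0384 with an estimated correlation), with ETV5 up by 0.94 (edgeR adjusted p 4.18e-06). Growth factor genes rose in 8 of 25 and fell in 1 (11 and 1 when adjusted over the list alone, 0.000559 with an estimated correlation). Spinous genes fell in 7 of 19 (8 when adjusted over the list alone, median -0.29, camera adjusted p 3.37e-07, and 0.0384 with an estimated correlation). KRT10 fell from 2690 to 1564 CPM (log2 fold change -0.78, edgeR adjusted p 1.74e-05). In the fit of TNF-α and medium alone neither ETV5 (0.109) nor KRT10 (0.1325) passed. Cornified envelope genes rose in 14 of 43 and fell in 1 (23 and 2 when adjusted over the list alone, camera adjusted p 6.80e-05), lost with an estimated correlation (0.376). Their median was 0.48, and 0.50 with the gene that had no counts in 1 of the groups at its bound.

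Other list calls in the TNF-α group were lost with an estimated correlation. Unfolded protein and ATF4 genes (8 of 18 higher, 2 lower, against 9 and 2 when adjusted over the list alone) and fatty acid synthesis genes (4 of 12 higher, 6 over the list alone) had camera adjusted p of 8.74e-05 and 0.00196, lost with an estimated correlation (0.335 and 0.0662). FADS3 rose from 47.7 to 80.3 CPM (edgeR adjusted p 1.54e-05, and 0.0866 in the fit of TNF-α and medium alone). The rise of FASN rested on TNF-α replicate 2, with a log2 fold change of 0.99 (edgeR adjusted p 0.0394) with it and 0.16 (0.448) without it. Its edgeR adjusted p was also 0.0737, 0.123 and 0.113 without medium replicates 1, 2 and 3. Calls for STAT3 targets, kallikreins, G2 and M phase genes and migration genes were lost without TNF-α replicate 2 (camera adjusted p 0.175, 0.178, 0.276 and 0.0630) and with an estimated correlation (0.381, 0.413, 0.607 and 0.356). S-phase and mesenchymal genes were lost without TNF-α replicate 3 (0.225 and 0.147) and with an estimated correlation (0.413 and 0.197). The antimicrobial list was lost without TNF-α replicate 1 (0.1103) or 3 (0.147), and the protease list likewise (0.1103 and 0.197) and also without medium replicate 1 (0.0850). With an estimated correlation both had an adjusted p of 0.381. Without TNF-α replicate 2, the camera adjusted p at the preset correlation was 2.07e-11 for unfolded protein and ATF4 genes (14 higher, 2 lower), 1.92e-07 for S-phase genes (13 higher, 1 lower) and 1.70e-05 for proteases (11 higher, 1 lower). It was then 7.67e-05 for the antimicrobial, 0.000382 for the mesenchymal and 0.00415 for the fatty acid synthesis list. The estimated correlation was not repeated without that library, so these values do not show whether the calls lost with it would hold. None of MET, IL17RA, IL17RC, IL22RA1, IL10RB and TNFRSF1A passed (edgeR adjusted p from 0.118 to 0.907), though IL17RC did without TNF-α replicate 1 (0.0211).

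IL-22 signals through IL22RA1 and IL10RB to the transcription factor STAT3. S100 proteins and STAT3 targets rose, and LORICRIN, FLG and KRT77 fell against medium. S100A7A rose from 0.312 to 14.4 ± 0.750 CPM (log2 fold change 5.50 ± 0.247, edgeR adjusted p 2.62e-13), S100A7 from 3.15 to 73.0 CPM (4.54, edgeR adjusted p 1.41e-10) and SOCS3 from 3.41 to 19.1 CPM (2.49, edgeR adjusted p 5.00e-10). Reads of the similar genes S100A7 and S100A7A may have been divided between them. KRT77 fell from 61.4 to 13.2 CPM (log2 fold change -2.22, edgeR adjusted p 2.41e-12), LORICRIN by 2.68 and FLG by 1.32 (edgeR adjusted p 0.00137 and 0.000317). SSPN, also among the 10 largest decreases (-1.47, edgeR adjusted p 0.0467), did not pass without any 1 of medium replicates 2 and 3 or of the IL-22 replicates (0.0534 to 0.221). The 312 genes called included 200 higher and 112 lower, and 78 changed at least 2-fold. This count was 194 without medium replicate 3, 194 without IL-22 replicate 1, 205 without IL-22 replicate 3 and 767 without TNF-α replicate 2. IL-22 and medium fitted alone gave 1634. Groups were separated for 4385 genes (28.2%, chance 10%).

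Of 18 antimicrobial and S100 genes, 11 rose with IL-22 and none fell (13 when adjusted over the list alone, median log2 fold change 1.22, and 1.07 with the gene that had no counts in 1 of the groups at its bound). The camera adjusted p was 7.80e-50, and 6.99e-06 with an estimated correlation. S100A9 rose from 267 to 1304 CPM (edgeR adjusted p 5.51e-06). STAT3 targets rose in 11 of 17 cases (13 when adjusted over the list alone, camera adjusted p 3.68e-45, and 2.21e-06 with an estimated correlation), with SERPINB4 up by 1.82 and LTB4R by 0.84. Spinous genes fell in 5 of 19 and rose in 1 (6 and 1 when adjusted over the list alone). Their median was only -0.02, but KRT1, KRT10 and DSC1 fell by 0.75, 0.87 and 0.72 (camera adjusted p 8.26e-09, and 0.0289 with an estimated correlation). The cornified envelope list was not called (6 of 43 higher, 5 lower, 7 and 7 when adjusted over the list alone, camera adjusted p 0.732). NF-κB genes (BCL3, also in the STAT3 list, up by 1.52), barrier lipid genes (6 of 22 lower, 2 higher) and mitochondrially encoded genes (0 of 13 passing) were called by camera but lost with an estimated correlation (adjusted p 0.0643, 0.495 and 0.830). The mitochondrial call (camera adjusted p 0.0162) was also lost without medium replicate 1 (0.0585) and without IL-22 replicate 3 (0.0551). MET and TNFRSF1A did not pass with all libraries (edgeR adjusted p 0.113 and 0.0605), but did with TNF-α replicate 2 left out (0.00145 and 0.00499).

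The IL100ng group, whose interleukin the labels do not name, changed 1738 genes against medium, 815 higher and 923 lower, and 206 at least 2-fold (edgeR). CSF2 rose from 0.272 to 2.51 ± 0.265 CPM (log2 fold change 3.16, edgeR adjusted p 4.74e-07), SAA1 from 3.22 to 13.4 CPM (2.06, edgeR adjusted p 5.58e-08) and TNF, the gene for TNF-α, from 1.75 to 5.44 CPM (1.63, edgeR adjusted p 3.02e-08). IGFBP3 fell to 127 ± 10.8 CPM (-1.90, edgeR adjusted p 6.10e-06) and OLFM2 from 33.7 to 10.9 CPM (-1.63, edgeR adjusted p 1.19e-08). MYH15 and RSAD2 were also among the 10 largest changes (1.78 and -1.66) but depended on single libraries. Without medium replicate 3 their edgeR adjusted p were 0.0820 and 0.161. MYH15 was also lost without IL100ng replicate 3 (0.0817), and RSAD2 without medium replicate 2 or any IL100ng replicate (0.0643 to 0.147). The total was 1158 without medium replicate 2, 1139 without medium replicate 3, 1126 without IL100ng replicate 1 and 3226 without TNF-α replicate 2. IL100ng and medium fitted alone gave 3328. Groups were separated for 5613 genes (36.1%, chance 10%).

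In the IL100ng group neutrophil chemokine, growth factor and mesenchymal genes rose and spinous genes fell. Neutrophil chemokine genes rose in 8 of 9 cases (9 when adjusted over the list alone, median log2 fold change 1.28, camera adjusted p 1.05e-12, and 0.000536 with an estimated correlation), while the list of other chemokines was not called (0.131). NF-κB genes rose in 9 of 19 and fell in 2 (11 and 2 when adjusted over the list alone), growth factor genes rose in 11 of 25 and fell in 1 (12 and 1), and mesenchymal genes rose in 5 of 11 (6). With an estimated correlation the camera adjusted p were 0.00205, 0.000536 and 0.00450. ICAM1 rose from 5.75 to 12.7 CPM and VIM from 136 to 248 CPM (edgeR adjusted p 1.66e-06 and 1.62e-05). Spinous genes fell in 11 of 19 (14 when adjusted over the list alone, median -0.48, 0.00205 with an estimated correlation). DSC1 fell by 1.09 (edgeR adjusted p 1.17e-07). Interferon genes fell in 18 of 30 (20 when adjusted over the list alone, median -0.45, camera adjusted p 2.88e-11), lost with an estimated correlation (0.112). S-phase genes (13 of 26 higher, 1 lower), ERK targets (13 of 27 higher, 2 lower) and unfolded protein and ATF4 genes (10 of 18 higher, 1 lower) had camera adjusted p of 9.72e-09, 9.44e-08 and 1.03e-06. They were lost with an estimated correlation (0.126, 0.106 and 0.126). Kallikreins, barrier lipids, fatty acid synthesis, protease and migration genes were also called and lost with an estimated correlation (0.164, 0.164, 0.0514, 0.310 and 0.185). The migration call was lost without IL100ng replicate 1 (0.0715) and medium replicate 2 (0.0501), and the protease call without medium replicate 1 (0.0698). Among the receptors none passed (edgeR adjusted p from 0.0508 to 0.841). IL17RC, the closest (log2 fold change -0.30), passed under several other choices, with an edgeR adjusted p of 0.0166 without TNF-α replicate 2 and 0.00965 in a fit of IL100ng and medium alone.

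Calcium is the usual switch for differentiation in cultured keratinocytes, and the comparison of 1.3 with 0.03 mM addresses that response. Keratins, cornified envelope genes and kallikreins rose, and genes of the unfolded protein response, growth factors and migration genes fell. KRT13 rose from 2.4 ± 0.157 to 148 ± 18.1 CPM (log2 fold change 5.94 ± 0.175, edgeR adjusted p 1.70e-17), KRT77 from 1.28 to 19.6 CPM (3.92, edgeR adjusted p 4.91e-15) and SPRR2G from 1.60 to 28.9 CPM (4.18, edgeR adjusted p 1.27e-13). HERPUD1 fell from 167 to 31.8 CPM (-2.40, edgeR adjusted p 6.81e-11) and HSPA5 from 2010 to 393 CPM (-2.36, edgeR adjusted p 3.15e-09). MMP1 and MMP3 fell by 2.95 and 2.53. In total 2321 genes were called, 1388 (59.8%) higher and 933 lower, and 502 changed at least 2-fold. With upper quartile scaling the higher share was 48.6%. The total was 1546 without low calcium replicate 2 and 3936 with TNF-α replicate 2 left out of the shared fit. Groups were separated for 5470 genes (35.2%, chance 10%).

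Differentiation lists rose together in high calcium. Spinous genes rose in 14 of 19 cases and fell in 1, cornified envelope genes rose in 27 of 43 and fell in 1, and kallikreins and their inhibitors rose in 10 of 11. When adjusted over the list alone the counts were 15 and 1, 35 and 2, and 11. Their median log2 fold changes were 0.88, 1.13 and 1.25, and with an estimated correlation the camera adjusted p were 0.000154, 0.00430 and 0.000981. KLK7 rose from 38.9 to 222 CPM (2.51, edgeR adjusted p 1.88e-12) and DSG1 from 237 to 601 CPM (1.34, edgeR adjusted p 7.97e-10). Keratins of the stress list rose in 8 of 9 cases in both adjustments (median 0.88, 0.00220 with an estimated correlation), with KRT6B up by 1.86 on the log2 scale (edgeR adjusted p 1.35e-11), though reads of the similar KRT6 genes may have been divided among them. Barrier lipid genes rose in 14 of 22 (16 when adjusted over the list alone, 0.0328 with an estimated correlation). Antimicrobial genes rose in 10 of 18 and fell in 1 in both adjustments, with SLPI and PI3 up by 2.88 and 2.96 (0.0194 with an estimated correlation).

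Unfolded protein and ATF4 genes fell in 15 of 18 cases with high calcium (17 when adjusted over the list alone, median log2 fold change -0.93, camera adjusted p 1.85e-30, and 0.000981 with an estimated correlation). Growth factor genes fell in 12 of 25 and rose in 1, ERK targets fell in 12 of 27 and rose in 2, and migration genes fell in 14 of 23 and rose in 1. When adjusted over the list alone the lower counts were 13, 14 and 15, and with an estimated correlation the camera adjusted p were 0.000154, 0.0335 and 0.00239. VEGFA fell from 206 to 88.6 CPM, DUSP6 from 128 to 60.6 CPM and TGFBI from 468 to 232 CPM (edgeR adjusted p 1.84e-09, 1.45e-09 and 1.23e-07). Protease, mesenchymal, basal keratinocyte and NF-κB lists and the list of the interleukin 20 family also fell (camera adjusted p with an estimated correlation 0.0328, 0.0284, 0.0328, 0.0379 and 0.0186). IL24 fell from 6.89 to 1.61 CPM (edgeR adjusted p 3.34e-09). The median of the interleukin 20 family was -0.65, and -0.80 with the gene that had no counts in 1 of the groups at its bound. Interferon, interleukin 1 family, p53 and mitochondrially encoded genes rose by camera (adjusted p 0.000131, 0.0364, 0.0364 and 0.000833), all lost with an estimated correlation (0.320, 0.435, 0.0587 and 0.385). Without high calcium replicate 2 the mitochondrial call held at a camera adjusted p of 0.0276. The interleukin 1 call was lost without low calcium replicate 2 (0.0727) or high calcium replicate 2 (0.138), and the p53 call without low calcium replicate 1 (0.0610) or high calcium replicate 3 (0.0661). MET did not pass (edgeR adjusted p 0.347, and 0.0437 without TNF-α replicate 2), and IL22RA1 rose by 0.38 (0.00664), which was lost without low calcium replicate 2 (0.0504).

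Low calcium was set beside medium to see whether the calcium groups can be read against the other 6. The difference was larger than that of any stimulus: 9234 genes were called, 4534 higher and 4700 lower, and 3090 changed at least 2-fold (edgeR). Groups were separated for 11207 genes (72.1%, chance 10%). FYB1 and OTOP2 had no counts in low calcium and were at 2.47 and 1.01 CPM in medium, at least 78.4-fold and 32.1-fold higher with a floor of 3 counts over the group. IGFBP3 fell from 474 to 5.22 ± 0.153 CPM (log2 fold change -6.50, edgeR adjusted p 2.25e-14), and CYP24A1 rose from 0.152 to 7.62 CPM (5.68, edgeR adjusted p 1.84e-13). Of the 43 cornified envelope genes 42 fell, of the 22 barrier lipid genes all fell, and of the 19 spinous genes 18 fell, in both adjustments (camera adjusted p with an estimated correlation 0.0124, 0.0217 and 0.00363). All 32 G2 and M phase genes rose (median log2 fold change 1.92, 0.00122 with an estimated correlation), with PLK1 up from 21.1 to 128 CPM (edgeR adjusted p 2.23e-17), and 25 of 26 S-phase genes rose (0.00874 with an estimated correlation). Calls for other chemokines, antimicrobial, interferon, kallikrein, basal, protease, ERK target, antigen presentation and p53 lists were lost with an estimated correlation (0.0606, 0.167, 0.1504, 0.443, 0.0606, 0.106, 0.469, 0.318 and 0.106). Of these, the ERK target call (camera adjusted p 0.0287) was lost without medium replicate 1 (0.0638). The antigen presentation call (0.0471) was lost without medium replicate 1 (0.05445), low calcium replicate 1 (0.0623) or replicate 3 (0.0537), and the p53 call (0.0486) without any low calcium replicate (0.0528 to 0.0623) or medium replicates 1 (0.05445) and 2 (0.05005). HLA-B fell from 521 to 172 CPM and CDKN1A from 698 to 338 CPM (edgeR adjusted p 2.26e-10 and 8.56e-09).

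**Figure D4:**
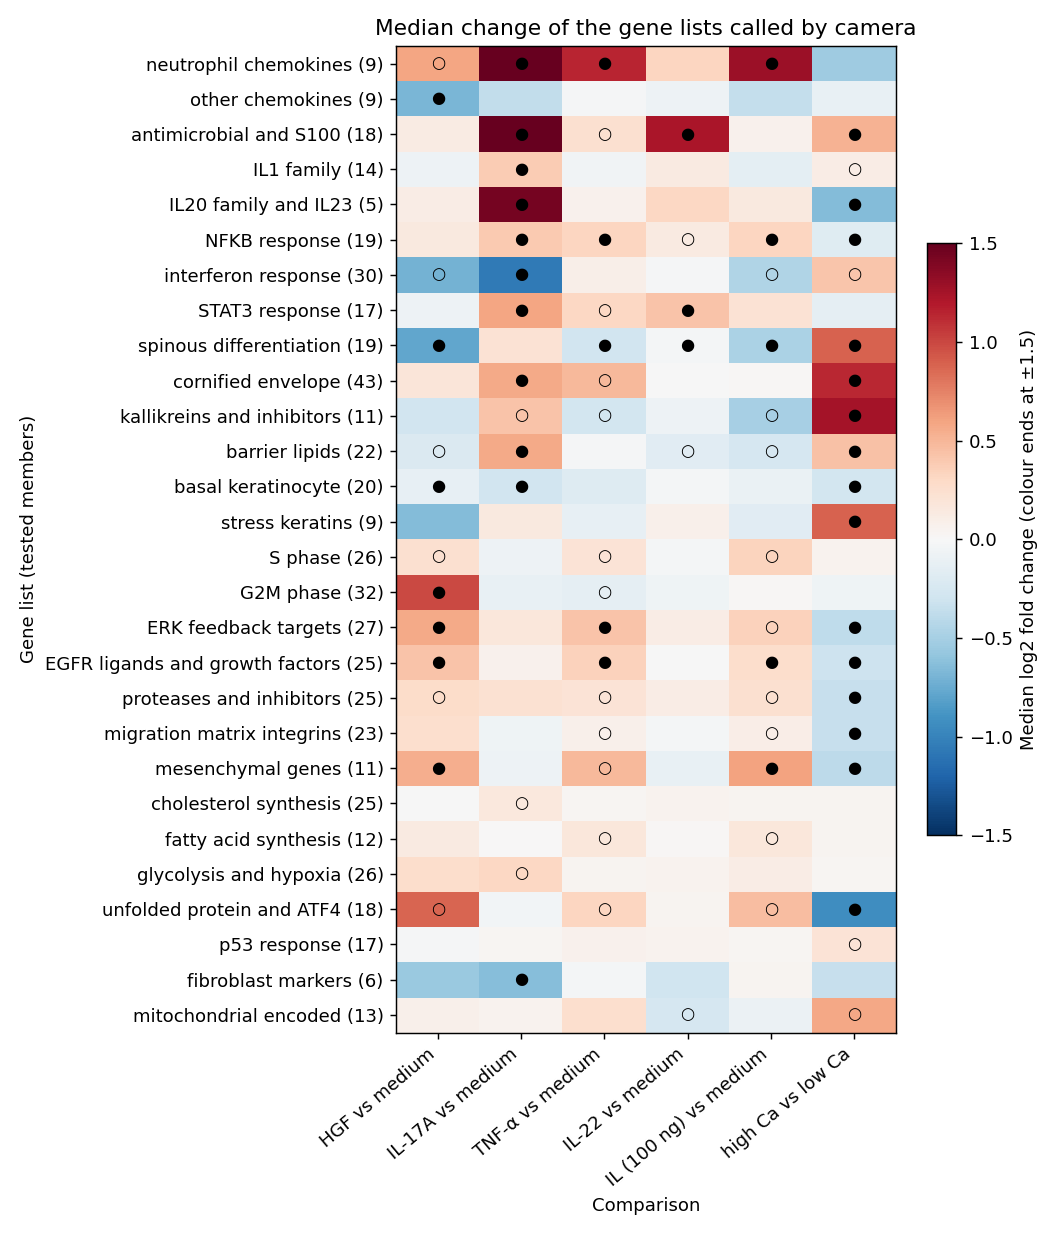
Colours show the median log2 fold change of each gene list (number of tested members in brackets) in 6 comparisons. Filled circles mark lists called by camera at an adjusted p under 0.05 both with the preset and with an estimated correlation, and open circles those called with the preset correlation only. The G2 and M phase list is at 0.99 in HGF and at -0.11 in IL-17A, and the antimicrobial list is at 3.15 in IL-17A and 1.22 in IL-22.

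The remaining lists were not called by camera in any of the 10 comparisons with all libraries. Their lowest camera adjusted p were 0.0636 for cytokine receptors (high against low calcium), 0.455 for melanocyte markers and 0.258 for endothelial markers. The calcium call for cytokine receptors passed without TNF-α replicate 2 (0.0376) and with upper quartile scaling (0.0448). By fry, which does not compare a list with other genes, all 3 were called in some comparisons, with lowest adjusted p of 5.69e-06, 0.00395 and 1.01e-06. Of the immune cell markers only 1 gene had enough counts, so that list was not tested.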

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

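Leaving out TNF-α replicate 2 was chosen after the data were seen for comparisons without the TNF-α group; it and all other alternatives were otherwise planned before the data were examined. Scaling with DESeq2 size factors or the upper quartile, both other filters, the DESeq2 Wald test and limma-voom kept every count of called genes within 1.5 times its value. The median over all genes moved by less than 0.1 (log2) under each scaling.

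With TNF-α replicate 2 left out, more genes were called: 5082 for IL-17A, 2503 for TNF-α, 767 for IL-22 and 3226 for IL100ng against medium, and 3936 for calcium. HGF then shared 3461 of 5537 genes with at least 1 other stimulus (1991 of 3845 with all libraries). With only the groups compared in the fit, the counts were 5844 for HGF, 6281 for IL-17A, 26 for TNF-α, 1634 for IL-22 and 3328 for IL100ng against medium, 214 for HGF against TNF-α, 193 for the distinct set and 3662 for the shared genes. The low counts all include the TNF-α group, whose 3 libraries hold the low-depth one; the cause was not tested further.

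For each count, 1 library at a time was left out among the groups that the count uses. This gave these ranges of called genes: 2840 to 3259 for HGF, 2301 to 2606 for IL-17A, 827 to 2503 for TNF-α, 194 to 222 for IL-22, 1126 to 1395 for IL100ng, 1546 to 2755 for calcium, 4372 to 4536 for HGF against IL-17A, 1678 to 3341 for HGF against TNF-α, 3042 to 3209 for HGF against IL-22, 8399 to 8482 for low calcium against medium, 870 to 1634 for the distinct set and 1427 to 3461 for the genes HGF shared. Counts that do not use the TNF-α group thus exclude the fit without TNF-α replicate 2, given above. List calls ranged from 132 to 161 over all 24 libraries. Within these ranges, beyond 1.5 times lay TNF-α without medium replicate 2 (827) or 3 (838) and TNF-α replicate 2 (2503), IL-22 without medium replicate 3 (194) or IL-22 replicates 1 (194) and 3 (205), IL100ng without medium replicates 2 (1158) and 3 (1139) and IL100ng replicate 1 (1126), calcium without low calcium replicate 2 (1546), and the shared genes without TNF-α replicate 2 (3461). Leaving out TNF-α replicate 2 also moved the IL-17A, IL-22, IL100ng and calcium counts beyond 1.5 times, with the values given above.

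Of 138 list calls by camera, 68 held with an estimated correlation and 132 with fry, which called 202 in all. With TNF-α replicate 2 left out 161 were called and 134 of the 138 held, at the preset correlation. The estimated correlation came from all 24 libraries in every comparison and was not repeated without TNF-α replicate 2. Whether that library accounts for calls lost with an estimated correlation was not tested. Over 1518 alternatives of the 138 calls, 1384 gave the same call, 134 did not pass and 0 reversed. Over 10830 alternatives of 774 results for named genes, 10516 gave the same call, 261 no longer passed, 53 newly passed and 0 reversed; 100 of the 261 came from fitting only the groups compared. Upper quartile scaling moved the share of higher genes from 45.9 to 32.4% for IL-17A and from 59.8 to 48.6% for calcium. No paired analysis was possible because the labels carry no replicate numbers that tie libraries of different groups together.

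Other splits of the 6 libraries of a comparison into 3 and 3 were also tested. With 10 splits, no share under 0.05 can be reached. The real split was 1 of 10 with as many genes in each comparison, and the highest other split called 0 genes in every comparison except HGF against TNF-α (2 against 2367). For the distinct set the numbers were 1182 and 0. Numbers of list calls were matched far more often. The real split and the highest other called 13 and 11 lists for HGF, 14 and 15 for IL-17A, 16 and 12 for TNF-α, 6 and 9 for IL-22, 14 and 14 for IL100ng, 19 and 16 for calcium, 20 and 15 for HGF against IL-17A, 9 and 15 for HGF against TNF-α, 13 and 13 for HGF against IL-22, and 14 and 13 for low calcium against medium. As many lists came from 1, 3, 1, 6, 2, 1, 1, 4, 2 and 1 of the 10 splits in that order. Every other split mixes libraries of both groups in unequal parts. It thus keeps part of any real difference and widens the spread within its groups. These splits therefore cannot show how many genes or lists chance alone would call. The number of camera calls at the preset correlation is not taken by itself as evidence of a difference between groups.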

Other observations

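In this part, the tests of the interferon pattern were written after the values were seen, and the bound for its first explanation was changed after a first run: to exclude it, the median had first to stay above -0.2 in both IL-22 and TNF-α, and later in either of them with any replicate left out. With the first form applied to each replicate left out, TNF-α (-0.241) would have left that explanation undecided. The glucocorticoid list was written before it was tested, but was prompted by FKBP5 and ZBTB16, which were left out of it. The other tests were written before their results.

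TNF-α replicate 2 stood apart from all libraries. Low depth alone may be set aside: thinning 1 of the other 2 TNF-α libraries to its total left them correlated at r = 0.981 across genes (0.981 to 0.982 over the draws), while TNF-α replicate 2 correlated with them at 0.933. Its extra mitochondrial ribosomal and other non-coding reads are not the whole cause either, since over 13660 nuclear protein-coding genes its r was 0.937 against 0.980 for the thinned libraries. Whether it carried the wrong label could not be settled. Over genes that differ between groups, its centred correlation was 0.0674 with the other TNF-α libraries, 0.0858 with medium and 0.0882 with IL100ng, a margin of -0.0209 that is too small to place it. A degraded or low-input library was not tested, and no biological explanation was tested.

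Interferon-response genes fell against medium with HGF, IL-17A and IL100ng (medians of -0.70, -1.06 and -0.45 on the log2 scale), 3 comparisons that share the medium libraries. With an estimated correlation the list call held for IL-17A (camera adjusted p 0.00265) and was lost for HGF (0.0537) and IL100ng (0.112). A raised interferon level in those libraries would lower the list in every group set against them. With IL-22 its median was -0.0213 (-0.0573 to -0.00318 with 1 replicate left out), which argues against that as the whole cause, unless IL-22 raised the list by a like amount. With TNF-α the median was 0.0866, but it ran from -0.241 to 0.288 with 1 replicate left out. HGF also lay below IL-22 for 24 of the 30 genes (median -0.83) and below TNF-α for 26, in tests that use no medium library, but neither list call held with an estimated correlation (adjusted p 0.0732 and 0.0609). More dividing cells would need the G2 and M phase list to rise alongside, and its median was 0.0175 in IL100ng (-0.0279 to 0.0587) and -0.107 in IL-17A, which argues against it as a cause common to the 3 groups. It stays open for HGF, where that list rose (median 0.99). In IL100ng 13 of 26 S-phase genes rose and 1 fell, but that list call was lost with an estimated correlation (camera adjusted p 0.126). Other technical explanations were not tested. An effect of the treatments themselves stays open as a hypothesis.

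Both calcium groups differed from medium in most genes, 9234 in low and 8986 in high calcium, with 7439 called in the same direction in both and 74 in opposite directions. If medium held a calcium concentration between the 2, its means should lie between theirs. For 96.3% of the genes called between low calcium and medium (95.0 to 96.4% with 1 replicate left out) medium lay outside both, so an intermediate calcium level cannot explain the difference as a whole. Another medium, donor, passage or day may do so, and cannot be told apart from the groups, since the labels give none of them and the study's design text does not describe the calcium cultures. One difference of medium was tried. FKBP5, chosen after its values were seen, was at 20.6 CPM in medium, 228 CPM in low and 284 CPM in high calcium, and ZBTB16, chosen likewise, had no counts in any of the 18 libraries outside the calcium groups and 0.619 and 0.685 CPM within them. Both are known to respond to glucocorticoids. A list of 12 other such genes had a median log2 fold change of 0.255 in low calcium (0.212 to 0.275) and 0.502 in high calcium. In low calcium 5 rose and 2 fell, and in high calcium 7 rose and 2 fell. Favouring a glucocorticoid in the calcium cultures needed a median above 0.5 in both groups, and excluding it a median at or below 0 in both. High calcium lay just above the first bound and low calcium between the 2, so a glucocorticoid cannot be told apart from other differences.

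The TNF-α and IL100ng groups were close to each other. A direct test, added after the data were seen, called 1 gene (edgeR), CXCL10, at 0.910 CPM in IL100ng and 4.25 CPM in TNF-α (log2 difference -2.23 ± 0.345, adjusted p 0.0172, and 0.0135 without TNF-α replicate 2). At an unadjusted p under 0.05 there were 1107 genes, and 803 without that library. Against medium the 2 groups shared 489 higher and 472 lower genes, with 1 opposite, where independent lists would share 40.1 and 37.3. Their log2 fold changes correlated at r = 0.645 across genes (simulated 0.431), with a covariance of 0.114 against 0.0330 simulated. The simulated groups held no real change, and their spread came from the fit that held TNF-α replicate 2. Chi-square per degree of freedom with IL100ng replicates 1, 2 and 3 was 13.7, 20.8 and 5.82 for TNF-α replicate 1 and 4.19, 7.895 and 11.8 for TNF-α replicate 3. It was 13.3 between TNF-α replicates 1 and 3, and 7.57, 8.75 and 12.9 within IL100ng. Whether labels were exchanged between the 2 groups was not tested.

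Most genes called in both the HGF and the calcium comparison changed in opposite directions, in 2 comparisons that share no library. Of the genes called in both, 481 were higher with HGF and lower with high calcium, where independent lists would share 119, and 580 were lower with HGF and higher with high calcium (166 if independent). Only 79 were higher in both (177 if independent) and 67 lower in both (112 if independent). Across genes r was -0.281. The opposition did not extend to the G2 and M phase list, which rose with HGF and was not called by camera for high against low calcium.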
